A study of Homo sapiens with 6 samples.

How the data were processed

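Total RNA of Huh7 cells was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, and the cells had received control or VersicanV1 knockdown lentivirus made in 293T cells, per the labels' protocols. The 6 libraries, 3 control and 3 knockdown, were grouped and numbered by their titles. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels name no batch or date.

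The authors deposited 1 table with 23344 rows, each a human Ensembl gene ID with a symbol, and 1 column per library. Its values are not counts: they are not whole, low values fall on steps that scale with gene length, and the libraries sum to totals from 851418 to 975501. They were treated as FPKM values made by the authors, although the deposited file does not name its unit, and TPM of an incomplete gene set is not excluded. The submitters' processing notes name bcl2fastq 2.19.0, Trimmomatic 0.36, Bowtie2 2.2.6, RSEM 1.1.17, edgeR 3.18.1 and DESeq2 1.16.1, without saying which step each was used for, and the genome build mm10. That is a mouse build, while each of the 23344 IDs is a human one, so the build the authors used stays uncertain and no coordinates are given. The annotation release is not given in the sources used here. Of the IDs, 22401 (96.0%) were found in GENCODE release 29, used here for gene types and transcript lengths alone. There were 5 rows at 0 in all libraries and 29 rows at 0 in some library and at 10 or more in another; an exact 0 can be a failed estimate.

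The test was planned for counts with a stated alternative for normalized values, and that alternative was used. Genes with a value of at least 1 in at least 3 libraries were kept (13696), a pseudocount of 1 was added, and log2 values were tested between groups with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, two-sided and with Benjamini-Hochberg adjustment over all genes tested. A fold change is on the log2(value + 1) scale, which understates the change of low genes. "Rose" and "fell" are used for genes with an adjusted p below 0.05. Each mean is followed by its SD where one is given, with n = 3 libraries per group. A test of this kind relies on a common prior for the spread of all genes, since 3 libraries against 3 give an exact permutation p of 0.1 at the smallest.

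Before the data were examined, 44 gene lists, the named-gene rule, the tests and most alternatives were fixed. The 41 lists with at least 5 genes tested were tested with limma's camera (preset correlation between genes of 0.01, two-sided, adjusted over lists), again with an estimated correlation, and with fry. Lists share members, so their tests are not independent. Genes were named by rule: fixed genes (VCAN, EGFR, PIK3CA, AKT1, AKT2, MKI67, CDH1 and VIM), the 12 largest rises and 12 largest falls among genes with an adjusted p below 0.05, a mean log2 value of at least 3, groups that do not overlap and no clone or pseudogene name, and up to 4 members with the smallest p in each list described. Genes named outside the rule are VCAN-AS1, MALAT1, OIP5-AS1, the fixed markers PTPRC and NKG7, and leukocyte genes said to be chosen after their values were seen. Some genes that the rule selects are not described, for reasons apart from their results.

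The deposited values give no read totals, so absolute depth is unknown and no counting intervals were computed. Relative depth was estimated from genes with a single annotated transcript of 500 to 3000 bases and a value from 0.1 to 1.5, as the lower 5% point of value times length, which would be the worth of 1 read per kilobase. It was between 0.0926 and 0.102 in the 6 libraries. Since values below 0.1 were left out, values of 1 read in a deeper library can drop out of this estimate. Alike estimates therefore do not show that depth was alike.

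The gene test was tested on simulated data drawn from the means and spreads of the 13696 genes, with 200 genes of a mean log2 value of at least 3 changed in each of 10 sets. It recovered 38.5% of genes changed 1.5-fold, 92.9% of those changed 2-fold and 99.5% of those changed 4-fold, and 6.63% of its calls were false, above the nominal 5%. These sets drew each gene independently and changed 200 genes, while 1107 were called in the real libraries. The rates need not hold there. In 20 further sets with independent genes, the camera test called a G2/M list lowered 1.5-fold in 20 and any list without a change in 0; genes in the real libraries are correlated, which these sets leave out. The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, leaving out each library in turn, both other list tests and, chosen after seeing the data, a rescaling of each library to its total without the 13 mitochondrially encoded genes. Alternatives planned for counts were not run.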

Results

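RNA sequencing was compared between Huh7 cells, an established human liver cancer line, that carried a control lentivirus and Huh7 cells that carried a lentivirus for knockdown of the V1 isoform of versican, a large chondroitin sulfate proteoglycan of the extracellular matrix encoded by VCAN. There were 3 libraries per group, and the knockdown libraries bear the label of a single hairpin. The comparison asks how transcript levels differ when versican is reduced, and the title of the series names proliferation, metastasis and the EGFR, PI3K and AKT genes as its subject. Values were treated as FPKM, although their unit is not named, and the number of reads per library is unknown. The values summed to 901697 ± 48313 (SD, n = 3) in control and 948977 ± 26690 (SD, n = 3) in knockdown libraries. From the low values of genes with a single annotated transcript, the depth of the libraries was estimated at 0.911 to 1 of that of the deepest one. Values below 0.1 were left out of that estimate, so it does not show that depth was alike.

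VCAN was lower in every knockdown library than in every control library. Its value was 4.79, 6.24 and 8.10 in control replicates 1, 2 and 3, and 1.90, 1.74 and 1.64 in knockdown replicates 1, 2 and 3. The control mean was 3.62 times the knockdown mean. The log2 fold change of VCAN (ENSG00000038427) was -1.39 (SE 0.19), with a limma adjusted p = 0.0103. Without control replicate 2 the log2 fold change was -1.40 and the adjusted p = 0.0537. The table has 1 row per gene, so the V1 isoform was not separated from the other versican isoforms. The antisense gene VCAN-AS1 was listed at 1.95 in control replicate 1 and at 0 in the other libraries.

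GDF15, a secreted stress-response cytokine, went from 26.9 ± 1.53 (SD, n = 3) in control to 191 ± 85.4 in knockdown (log2 fold change 2.70, SE 0.26, adjusted p = 0.00501). GBP1, an interferon-inducible GTPase, had the largest rise of the named genes (3.11, SE 0.67, adjusted p = 0.0440), from a mean of 6.05 to 75.7, with 18.6 in knockdown replicate 1 and 88.6 and 120 in knockdown replicates 2 and 3. TM4SF4, a tetraspan membrane protein, rose by 2.58, F3, which encodes tissue factor, by 2.43, and RASD1, a Ras-related GTPase, by 2.32 on the log2 scale. NNMT, nicotinamide N-methyltransferase, also rose by 2.32, TMEM27, a collectrin gene, by 2.25, and the deubiquitinase gene OTUD1 rose from 8.08 to 46.7. The transcription factor genes MAFF and ATF3 rose by 2.16 and 2.04. AREGB went from 33.2 ± 5.21 to 140 ± 14.5 (2.05, SE 0.14, adjusted p = 0.000943); it is a near-identical copy of the amphiregulin gene, so the copy from which the reads came is uncertain. Over 11 alternatives GBP1 and ATF3 passed in 4 each, OTUD1 in 5 and NNMT in 6, with an adjusted p of up to 0.156 for GBP1.

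CA3, which encodes carbonic anhydrase III, went from 136 ± 20.9 (SD, n = 3) to 33.8 ± 2.83 (log2 fold change -1.97, SE 0.14, adjusted p = 0.000943). The bile acid receptor gene NR1H4 fell by 1.47 and the hepatocyte transcription factor gene CEBPA by 1.36 on the log2 scale. HERC3, a ubiquitin ligase gene, fell by 1.58, NTS, which encodes neurotensin, by 1.54, and the transcription factor gene SOX13 by 1.46. The long non-coding RNA DANCR fell by 1.30, and NT5E, the ecto-5'-nucleotidase gene, by 1.27. RRM2, the small subunit of ribonucleotide reductase, fell by 1.24, OLR1, a receptor for oxidized low-density lipoprotein, by 1.24, and PRMT5, an arginine methyltransferase gene, by 1.23. MT1A fell by 1.19, and as one of several near-identical metallothionein genes its reads are uncertain. Over 11 alternatives RRM2 passed in 2, with an adjusted p of up to 0.162, MT1A in 4, and NT5E and DANCR in 5 each; of 120 called genes that the naming rule selects and the alternatives cover, 105 lost the call in at least 1 alternative. The plot of named genes shows the value of each in every library.

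**Figure D1:**
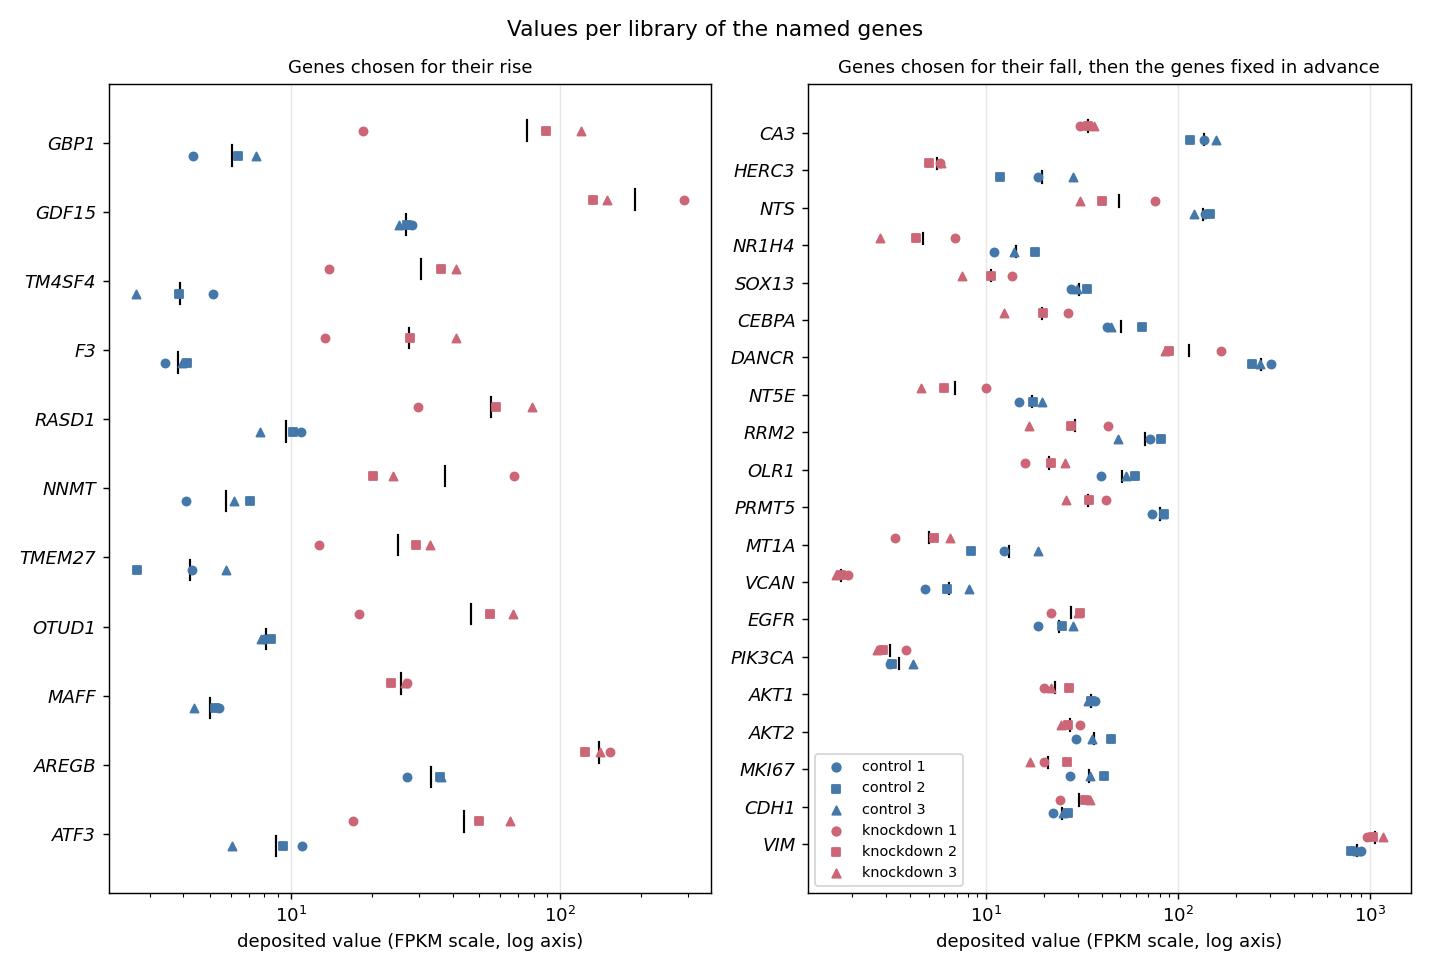
Deposited values (treated as FPKM, log axis) per library of the named genes. The left panel holds the 11 genes named for their rise. The right panel holds the 12 named for their fall, followed by 8 genes fixed in advance. Blue points are control and red points knockdown libraries, symbols mark replicates 1 to 3 and black ticks group means; VCAN lies between 4.79 and 8.10 in control and between 1.64 and 1.90 in knockdown libraries, while the values of EGFR overlap.

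In all, 1107 of 13696 genes tested changed (limma, Benjamini-Hochberg adjusted p below 0.05), 568 higher and 539 lower in the knockdown libraries, and 894 of these changed by at least 1.5-fold (526 higher, 368 lower). The groups were fully apart for all of the 1107 genes and for 33.1% of all genes tested. The average over all splits of the libraries into 3 and 3 would be 10%. Genes are correlated, so a single split can exceed that by chance, and the share is weak evidence on its own. The count of changed genes depended on which libraries entered the test. It was 166, 56 and 244 without control replicates 1, 2 and 3, 3284 without knockdown replicate 1, and 111 and 194 without knockdown replicates 2 and 3. It was 221 with no filter on low values. When each library was rescaled to its total without the mitochondrially encoded genes, an alternative chosen after seeing the data, 680 genes were higher and 223 lower. The median log2 fold change of all genes tested was then 0.0633, against -0.0291 without the rescaling.

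Genes of the cell division cycle were lower in the knockdown libraries. Of 32 G2/M and mitosis genes, 19 fell and 0 rose, and 28 fell when adjusted over the list alone, with a median log2 fold change of -0.69. BIRC5, which encodes survivin, fell (-0.87, SE 0.14, adjusted p = 0.0154), BUB1, a spindle checkpoint kinase gene, from 27.3 to 13.3 (-0.99, adjusted p = 0.0255), and NUSAP1 and NDC80, genes of the spindle and kinetochore, by 0.71 and 0.76. Of 32 G1/S and DNA replication genes, 8 fell and 0 rose, and 23 fell when adjusted over the list alone, with a median of -0.56. MCM6, MCM3 and MCM4, subunits of the replicative helicase, fell by 0.97, 0.71 and 0.80, and RRM1, the large subunit of ribonucleotide reductase, by 0.69. The proliferation marker MKI67 had 34.4 ± 6.93 in control and 21.1 ± 4.86 in knockdown libraries and did not pass the test (-0.69, SE 0.20, adjusted p = 0.0635). Among 13 CDK inhibitors, D cyclins and partners, the inhibitor genes CDKN2B and CDKN1A rose (1.48 and 0.79), while the kinase gene CDK2 (-0.69) and the inhibitor gene CDKN2C (-1.09) fell; 2 rose and 5 fell when adjusted over the list alone, and the list had a median of -0.31 and was not called (camera adjusted p = 0.140).

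For the G2/M list the camera adjusted p was 1.58e-12, with adjusted p = 0.339 with an estimated correlation between genes. For the G1/S list the adjusted p was 1.53e-10, with adjusted p = 0.362 with an estimated correlation. Against the control mean, the G2/M list averaged -0.43, -0.57 and -0.94 in knockdown replicates 1, 2 and 3, and between -0.10 and 0.14 in the control libraries. The number of G2/M genes past the threshold was 0, 0 and 2 without control replicates 1, 2 and 3, 28 without knockdown replicate 1, and 1 without either knockdown replicate 2 or 3, and that of G1/S genes was 0, 0 and 1, then 25, 2 and 1, in the same order. With all libraries kept, the G2/M and G1/S counts were 1 and 1 with no filter on low values, 13 and 4 with quantile normalization, 11 and 3 with the rescaling without mitochondrially encoded genes, and 19 and 14 with the replicate block.

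EGFR had 23.9 ± 4.80 (SD, n = 3) in control and 27.6 ± 4.99 in knockdown libraries, a difference within the spread between replicates (log2 fold change 0.20, SE 0.19, adjusted p = 0.509). PIK3CA (-0.12, adjusted p = 0.677) and AKT2 (-0.39, adjusted p = 0.161) did not pass the test either. AKT1 fell from 35.3 ± 1.44 to 22.9 ± 3.63 (-0.61, SE 0.13, adjusted p = 0.0334). Its adjusted p was between 0.0183 and 0.122 over 11 alternatives, and it did not pass in 8 of them, which included every one that left out a library other than knockdown replicate 1.

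Of 10 ERBB receptors, ligands and regulators tested, 2 rose and 0 fell, and 4 rose when adjusted over the list alone, with a median of 0.24. The 2 genes were EREG, which encodes the ligand epiregulin (5.81 to 17.3, log2 fold change 1.47, adjusted p = 0.0109), and ERRFI1, which encodes an inhibitor of EGFR that is induced by EGFR signalling (24.8 to 44.3, 0.81, adjusted p = 0.0164). The list was called higher (camera adjusted p = 0.0136), with adjusted p = 0.339 with an estimated correlation. AREG, the gene of the ligand amphiregulin, was not among the 10 genes tested. AREGB, its near-identical copy, was not in the list and rose from 33.2 to 140 (log2 fold change 2.05, limma adjusted p = 0.000943). Of 29 PI3K-AKT-mTOR pathway components, RICTOR, a subunit of mTOR complex 2, rose (0.66, adjusted p = 0.0353) and AKT1 fell, and the counts were the same when adjusted over the list alone. The median of that list was -0.11 (camera adjusted p = 0.624), and it was 0.001 after the rescaling without mitochondrially encoded genes. Of 23 FOXO target genes, 4 rose and 0 fell, and 5 rose when adjusted over the list alone (median 0.20, camera adjusted p = 0.000430, with adjusted p = 0.339 with an estimated correlation). These were TRIB1 (1.03), CDKN1A (0.79), PIK3IP1 (1.00 to 4.66, 1.44), which encodes an inhibitor of PI3K, and RICTOR. Transcript levels do not measure the activity of these kinases.

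Genes induced by NF-kB and by acute stimuli were higher in the knockdown libraries. Of 20 NF-kB and inflammatory genes, 10 rose and 0 fell, and 15 rose when adjusted over the list alone, with a median of 1.12. IL8, a neutrophil chemokine gene, rose from 68.6 ± 9.21 to 251 ± 36.0 (1.85, SE 0.15, adjusted p = 0.00190), and the chemokine gene CCL20 from 698 ± 146 to 1560 ± 254 (1.17, SE 0.18, adjusted p = 0.0150). BIRC3, an apoptosis inhibitor gene, and RELB, an NF-kB subunit gene, rose by 1.89 and 1.98. Of 19 immediate early genes, 7 rose and 0 fell, and 11 rose when adjusted over the list alone, with a median of 0.78. These included JUNB (57.6 to 171, 1.59), KLF4 (0.83), ZFP36 (0.78) and DUSP1 (0.86). Of 19 ERK-MAPK output genes, 5 rose and 1 fell, and 8 rose and 3 fell when adjusted over the list alone (median 0.19, camera adjusted p = 0.0693). DUSP5, PHLDA2, SPRY2 and PHLDA1 rose by 1.55, 1.08, 0.71 and 0.72; the list median was -0.02 without knockdown replicate 1, and the list passed without control replicate 2 or without knockdown replicate 2 or 3, its adjusted p ranging from 0.0101 to 0.629.

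The NF-kB list had a camera adjusted p of 3.54e-11, with adjusted p = 0.276 with an estimated correlation. The immediate early list had an adjusted p of 2.42e-07, with adjusted p = 0.248 with an estimated correlation. Against the control mean, the NF-kB list averaged 0.68, 1.03 and 1.29 in knockdown replicates 1, 2 and 3. The number of NF-kB genes that rose was 2, 2 and 7 without control replicates 1, 2 and 3, 15, 3 and 5 without knockdown replicates 1, 2 and 3, and 4 with no filter on low values. Of 20 interferon response genes, 1 rose and 0 fell, IFITM3 (0.85, adjusted p = 0.0172), and 6 rose when adjusted over the list alone (median 0.23, camera adjusted p = 0.00960, with adjusted p = 0.339 with an estimated correlation). ISG20, IRF9 and CXCL10 had log2 fold changes of 0.86, 0.67 and 1.72 and did not pass. Transcripts of blood cells were present in knockdown replicate 2. There, S100A9 was at 30.6, S100A8 at 17.9 and NKG7 at 5.54, against at most 4.13, 0 and 0.1 in any other library; S100A9 and S100A8 were chosen after their values were seen.

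**Figure D2:**
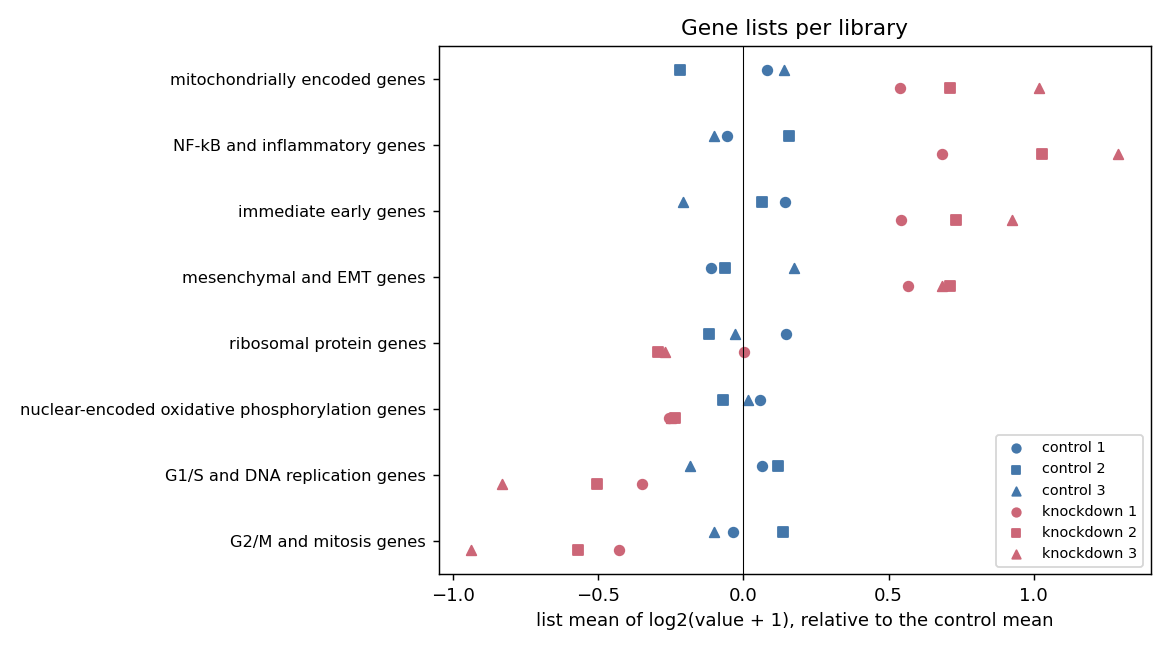
Mean of log2(value + 1) over the members of 8 gene lists in each library, relative to the mean of the control libraries (horizontal axis, log2 units). Blue points are control and red points knockdown libraries, with symbols for replicates 1 to 3; the G2/M list lies at -0.43, -0.57 and -0.94 and the NF-kB list at 0.68, 1.03 and 1.29 in knockdown replicates 1, 2 and 3.

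Several genes of the extracellular matrix and of mesenchymal cells were higher in the knockdown libraries. Of 20 mesenchymal and EMT genes, 7 rose and 0 fell, and 13 rose when adjusted over the list alone, with a median of 0.63. COL1A2, a type I collagen gene, rose from 8.32 ± 1.83 to 23.1 ± 2.18 (1.38, SE 0.16, adjusted p = 0.00770), FN1, which encodes fibronectin, from 590 ± 68.3 to 914 ± 48.2 (0.64), and the transcription factor gene ZEB2 (1.14) and the integrin gene ITGA5 (14.9 to 35.8) rose as well. VIM, which encodes vimentin, had 853 ± 50.9 and 1056 ± 104 and did not pass (0.31, adjusted p = 0.121). CDH1, the E-cadherin gene, had 24.7 ± 2.17 and 30.5 ± 5.60 and did not pass (0.28, adjusted p = 0.274). Of 22 epithelial genes, the claudin genes CLDN7 (0.97) and CLDN4 (0.84) rose and the keratin gene KRT8 (-0.58) fell, with the same counts when adjusted over the list alone. The epithelial median was -0.007, its mean was 0.02 and camera's direction was up (adjusted p = 0.501), and the median was above 0 with quantile normalization and with the rescaling without mitochondrially encoded genes.

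Of 18 basement membrane and fibrillar matrix genes, 5 rose and 0 fell, and 7 rose when adjusted over the list alone (median 0.25). COL11A1 rose from 3.44 to 16.1 (1.98, SE 0.21, adjusted p = 0.00648), the laminin gene LAMB3 rose from 0.527 to 2.29, and COL1A1 and LAMB2 rose by 0.76 and 0.82. Of 15 matrix metalloproteinases, ADAMTS proteases and inhibitors, 4 rose and 0 fell, and 5 rose and 1 fell when adjusted over the list alone (median 0.35). Of these 4, TIMP1, TIMP2 and TIMP3, which encode inhibitors of metalloproteinases, rose by 1.03, 1.06 and 1.24, and the protease gene ADAMTS1 by 0.63. Of 20 TGF-beta response genes, 7 rose and 1 fell, and 10 rose and 4 fell when adjusted over the list alone (median 0.63), with TGFB2 and TGFBR1 higher by 0.97 and 0.64. Of 19 proteoglycans, hyaluronan genes and versican partners, 0 rose and 4 fell, and 5 rose and 4 fell when adjusted over the list alone. Besides VCAN these were the syndecan genes SDC1 (20.7 to 9.89) and SDC2 (-0.43) and the hyaluronan receptor gene HMMR (-0.79), which is also a member of the G2/M list. That list's median was 0.09, its mean was -0.005 and it was not called (camera adjusted p = 0.526).

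The camera adjusted p of the mesenchymal list was 2.42e-07, with adjusted p = 0.248 with an estimated correlation, and that of the basement membrane list was 0.000430, with adjusted p = 0.339 with an estimated correlation. The metalloproteinase list had an adjusted p of 0.0184, with adjusted p = 0.391 with an estimated correlation, and the TGF-beta list one of 0.00320, with adjusted p = 0.248 with an estimated correlation. The number of mesenchymal genes that rose was 1, 1 and 4 without control replicates 1, 2 and 3, 10, 1 and 1 without knockdown replicates 1, 2 and 3, and 1 with no filter on low values. The metalloproteinase call was lost with no filter on low values (adjusted p = 0.0517) and without knockdown replicate 2 (adjusted p = 0.0513), and its adjusted p ranged from 0.00306 to 0.0517 over 11 alternatives.

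Genes of the hepatocyte program went in both directions. Of 31 hepatocyte secreted proteins, 8 rose and 2 fell, and 13 rose and 3 fell when adjusted over the list alone (median 0.39). The fibrinogen genes FGG and FGB rose from 646 ± 3.78 to 1027 ± 29.6 (0.67) and from 1529 ± 163 to 2478 ± 190 (0.70), and the coagulation factor gene F7 rose by 0.66, while TTR, which encodes transthyretin, fell (-1.19, SE 0.14, adjusted p = 0.00770). Of 17 acute phase genes, 6 rose and 0 fell, and 7 rose and 2 fell when adjusted over the list alone (median 0.28), with SERPINA3 (1.42) and CP (1.17) beside the fibrinogen genes shared by both lists. Of 20 liver transcription factors, 4 fell and 1 rose, and 5 fell and 2 rose when adjusted over the list alone (median -0.17). The 4 that fell were FOXA1 (-0.89), FOXA3 (-0.68), NR1H4 and CEBPA. Of 19 hepatocyte metabolic enzymes, UGT2B7 (1.09), BAAT (2.04) and CYP3A5 (1.43) rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (median 0.09).

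The secreted protein list had a camera adjusted p of 0.000476, with adjusted p = 0.542 with an estimated correlation, and the acute phase list one of 0.00370, with adjusted p = 0.248 with an estimated correlation. The lists of transcription factors (adjusted p = 0.0731) and metabolic enzymes (adjusted p = 0.140) were not called by camera. With an estimated correlation they had an adjusted p of 0.362 and 0.496. Fry called the transcription factor list lower (adjusted p = 0.0388). With no filter on low values both lists passed camera, at adjusted p = 0.0380 and 0.0315. Their adjusted p ranged from 0.0380 to 0.204 and from 0.0315 to 0.302 over 11 alternatives.

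Transcripts encoded by the mitochondrial genome took a larger share of the knockdown libraries. Their share of all values was 17.5%, 15.98% and 19.2% in control replicates 1, 2 and 3 and 23.8%, 27.0% and 31.2% in knockdown replicates 1, 2 and 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). Of the 13 genes, 12 rose and 0 fell, and 13 rose when adjusted over the list alone, with a median of 0.72. MT-ND3 rose from 6362 ± 1046 to 12444 ± 1652 (0.97, SE 0.15, adjusted p = 0.0150), and MT-CYB, MT-CO3 and MT-ND2 rose by 0.96, 0.79 and 0.69. The number of mitochondrially encoded genes that rose was 2, 0 and 1 without control replicates 1, 2 and 3, 13, 0 and 1 without knockdown replicates 1, 2 and 3, 6 with quantile normalization and 1 with no filter on low values. Of 34 nuclear-encoded oxidative phosphorylation genes, 0 rose and 4 fell, and 9 fell when adjusted over the list alone (median -0.23). These included ATP5A1 (-0.48), CYC1 (-0.47) and NDUFA9 (-0.50). The number of them that fell was 0 with no filter, with quantile normalization, with the replicate block, with the rescaling without mitochondrially encoded genes and without any 1 library other than knockdown replicate 1, without which it was 10. Of 22 glycolysis genes, ALDOA (1210 to 689, -0.85), PGAM1 (-0.46) and LDHA (-0.40) fell and 0 rose, and 7 fell when adjusted over the list alone (median -0.21). Of 52 ribosomal protein genes, 1 fell and 0 rose, and 0 passed when adjusted over the list alone (median -0.16). Of 25 ribosome biogenesis and nucleolar genes, 0 passed the limma test in either direction, nor did any when adjusted over the list alone, with a median of -0.25. Against the control mean this list averaged 0.18 in knockdown replicate 1, above each control library, and -0.41 and -0.51 in knockdown replicates 2 and 3.

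The mitochondrially encoded list had a camera adjusted p of 1.09e-09, with adjusted p = 0.339 with an estimated correlation, and the nuclear oxidative phosphorylation list one of 1.88e-05, with adjusted p = 0.321 with an estimated correlation. The glycolysis list had an adjusted p of 0.0404, with adjusted p = 0.339 with an estimated correlation. Those of ribosomal proteins (adjusted p = 0.000408) and of ribosome biogenesis (adjusted p = 0.0241) both had an adjusted p = 0.682 with an estimated correlation. Quantile normalization ended the calls of the glycolysis, ribosomal protein and ribosome biogenesis lists (adjusted p = 0.0744, 0.178 and 0.0744), and no filter on low values that of the glycolysis list (adjusted p = 0.153). Their adjusted p ranged from 0.0230 to 0.153, from 1.48e-07 to 0.178 and from 2.24e-07 to 0.276 over 11 alternatives, in that order. Leaving out libraries ended the glycolysis call without control replicate 1 or 2 or knockdown replicate 2 or 3, the ribosomal protein call without control replicate 1 or knockdown replicate 2, and the ribosome biogenesis call without control replicate 2 or knockdown replicate 2 or 3.

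Over the 41 lists with at least 5 genes tested, camera called 22, of which 16 were higher and 6 lower. With an estimated correlation it called 0, with 6 at an unadjusted p below 0.05 and a smallest adjusted p = 0.248, and fry called 15. The 15 included the lists of liver transcription factors, apoptosis regulators and packaging cell markers, which camera did not call. Fry did not call the G1/S, ribosomal protein, FOXO, hepatocyte secreted protein, interferon, ERBB, metalloproteinase, ribosome biogenesis, histone and ATF4 lists, which camera called. Other splits of the 6 libraries into 3 and 3 gave up to 19 called lists with the preset correlation, so the number of called lists is weak evidence on its own. The number of genes changed was 0 in each of those splits, which put the group difference into the spread within groups. The plot of list members shows how far single genes spread around each median.

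**Figure D3:**
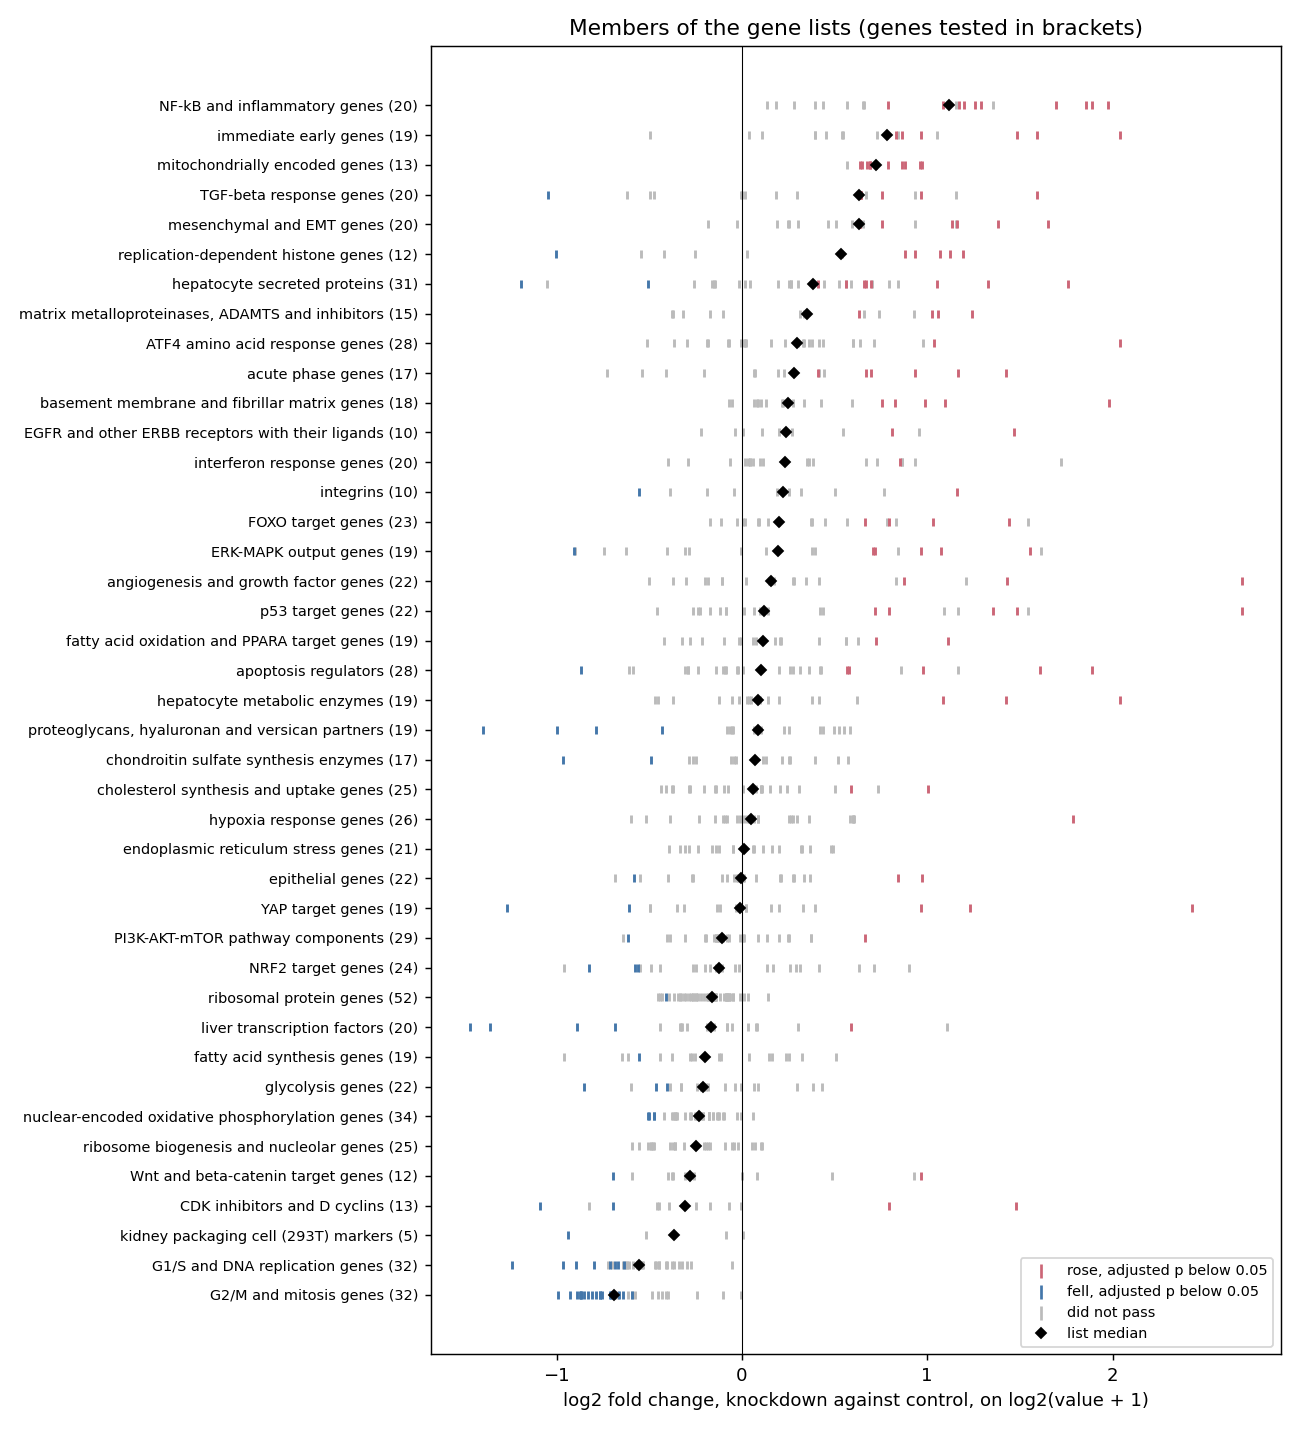
Log2 fold change, knockdown against control, of each tested member of 41 gene lists (horizontal axis, log2(value + 1) scale), with red ticks for genes that rose, blue ticks for genes that fell, grey ticks for genes that did not pass and a black diamond at the list median. Medians run from -0.69 for the G2/M list to 1.12 for the NF-kB list.

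The libraries within a group were not alike. The mitochondrially encoded share (23.8%, 27.0% and 31.2%) and the nuclear-retained RNA MALAT1 (361, 491 and 638) increased from knockdown replicate 1 to 3. The G2/M, G1/S, immediate early and NF-kB lists lay farther from the control mean in the same order. The mesenchymal list (0.57, 0.71 and 0.68) and the TGF-beta list (0.40, 0.34 and 0.33) did not follow that order. Lists that ran the opposite way included ATF4 amino acid response genes (0.62, 0.19 and 0.06) and ERK-MAPK output genes (0.57, 0.09 and 0.03). VCAN was lower in that order too (1.90, 1.74 and 1.64). These steps were small beside its control range of 4.79 to 8.10 and were not tested. Library composition and the extent of the knockdown thus cannot be told apart over these 3 libraries. Pearson correlations of log2(value + 1) over tested genes were 0.982 to 0.985 between control libraries, 0.987 between knockdown replicates 2 and 3, and 0.975 and 0.970 between knockdown replicate 1 and those. Markers of other cell types were examined as well, and some were well expressed in every library. Of 13 leukocyte markers, 4 were expressed at 1 or more in a control library and 4 entered the test, of which LYZ, which encodes lysozyme, rose (22.6 to 50.2, 1.08, adjusted p = 0.0277). PTPRC, a pan-leukocyte gene, was at 1.96 in knockdown replicate 2 and at most 0.16 elsewhere. Of 4 fibroblast and stellate cell markers tested, COL1A2 and COL1A1 rose, and 0 endothelial markers could be tested. Of 5 markers of kidney packaging cells tested, HOXA9 fell (-0.94, adjusted p = 0.0250) and 0 rose, and 2 fell when adjusted over the list alone (median -0.37, camera adjusted p = 0.0765). Fry called this list lower, with the smallest adjusted p of all lists (0.00410), while camera with an estimated correlation gave adjusted p = 0.339. The packaging cell markers not tested were at most 1.12 in any library, and HOXA9 was at 2.03 or more in each. A lower list thus need not mean less RNA of packaging cells.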

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

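The rescaling without mitochondrially encoded genes was chosen after the results were seen; the other alternatives were planned. The VCAN log2 fold change stayed negative in 11 alternatives and past the threshold in 10, and ranged from -1.56 to -1.23 when single libraries were left out. Leaving out single libraries moved the number of genes changed between 56 and 3284 and that of genes changed at least 1.5-fold between 56 and 2072, with fewer libraries in each test; that the number rose without knockdown replicate 1 goes with its lower correlation with the other knockdown libraries. With no filter on low values, which adds genes near 0 to the test, 221 genes changed, 214 of them at least 1.5-fold. Called lists went from 22 to 0 with an estimated correlation, which was 0.67 for the G2/M list in place of the preset 0.01. The PI3K-AKT-mTOR median was 0.00101 after the rescaling. That rescaling moved the median of all genes tested from -0.0291 to 0.0633, so the whole scale shifted upward with it. The G2/M and ERBB list calls held in 11 alternatives with the preset correlation. Of the 23 genes named for their rise or fall, 4 passed in each of 11 alternatives (GDF15, MAFF, AREGB and CA3).

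Reversals were small and none passed the threshold, and their cause was not tested. With quantile normalization the log2 fold change was 0.0415 for LUM and 0.0347 for CKB, and the median 0.0212 for epithelial and 0.0639 for YAP target genes. With the rescaling, which also shifted the median of all genes tested upward, these were 0.0434, 0.0200, 0.0940 and 0.0989. With no filter the epithelial median was 0.00564. Leaving out single libraries gave ranges of -0.112 to 0.00252 for LUM, -0.186 to 0.0833 for CKB, -0.280 to 0.0789 for CD68, and list medians of -0.0415 to 0.0673 for epithelial genes, -0.0436 to 0.0602 for endoplasmic reticulum stress genes, -0.0273 to 0.0471 for YAP target genes, -0.102 to 0.0983 for cholesterol genes, -0.0196 to 0.332 for ERK-MAPK output genes and -0.0106 to 0.216 for apoptosis regulators. Over 173 named genes, alternatives that kept all libraries gave the same direction and the same side of the threshold in 723 of 865 comparisons. They lost a call in 125, gained one in 13 and reversed the direction in 4. Leaving out libraries gave 572, 411, 32 and 5 of 1020, in the same order.

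With the replicate block 861 genes changed in place of 1107. The labels do not say that the numbers pair the samples, and the values leave it open: deviations of same-numbered libraries from their group means correlated weakly, at 0.053, 0.105 and 0.135. Control replicates 2 and 3 each correlated best with the same-numbered knockdown library, and control replicate 1 with knockdown replicate 3 (0.0803). Alternatives that need counts (other count normalizations and filters, voom and the count tests) were not run because the values are not counts. Absolute depth is unknown, which limits what can be said of values near 0.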

Other observations

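Further lists fixed before the data were examined held changes in both directions. Of 22 p53 target genes, 5 rose and 0 fell, and 9 rose when adjusted over the list alone: besides GDF15 and CDKN1A these included PLK3 (1.36) and BTG2 (1.48), with a median of 0.12 (camera adjusted p = 0.00822, with adjusted p = 0.248 with an estimated correlation). Of 28 apoptosis regulators, 5 rose and 1 fell, and 8 rose and 2 fell when adjusted over the list alone. BIK, a pro-apoptotic gene, rose by 1.61, and BCL2A1, an anti-apoptotic gene, by 0.98, at low values (0.0633 to 1.09). The list median was 0.10 (camera adjusted p = 0.0739, with adjusted p = 0.339 with an estimated correlation, fry adjusted p = 0.0477). Of 28 ATF4 amino acid response genes, PPP1R15A (1.04) and ATF3 rose and 0 fell, with the same count when adjusted over the list alone (median 0.30, camera adjusted p = 0.0281, with adjusted p = 0.475 with an estimated correlation), and the call was lost without control replicate 1 or 3, without knockdown replicate 1 and with no filter, the adjusted p ranging from 0.000361 to 0.642 over 11 alternatives. Of 21 endoplasmic reticulum stress genes, 0 passed the limma test over all genes or over the list alone (median 0.01, camera adjusted p = 0.624). Of 24 NRF2 target genes, 3 fell, among them PIR (-0.56) and NQO1 (-0.82), and 0 rose, and 5 fell and 1 rose when adjusted over the list alone (median -0.12, camera adjusted p = 0.348, past the threshold without knockdown replicate 1, range 0.0230 to 0.852). Of 22 angiogenesis and growth factor genes, GDF15, IGFBP2 (1.43) and PDGFA (0.87) rose and 0 fell, and 4 rose when adjusted over the list alone (median 0.16, camera adjusted p = 0.0281, with adjusted p = 0.320 with an estimated correlation; lost without control replicate 3, without knockdown replicate 1 and with no filter, range 0.00752 to 0.0915). Of 12 replication-dependent histone genes, 5 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone, with HIST1H2BK (1.19) higher and HIST2H2AC (6.74 to 2.82) lower (median 0.54, camera adjusted p = 0.0266, with adjusted p = 0.421 with an estimated correlation; lost without knockdown replicate 1, with no filter and with the rescaling, range 0.00128 to 0.121); reads of these near-identical genes are uncertain.

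Camera called 0 of the lipid and signalling lists below. Of 25 cholesterol synthesis and uptake genes, 2 rose, among them SREBF2 (0.59), and 0 fell, and 2 rose and 1 fell when adjusted over the list alone (median 0.06, camera adjusted p = 0.560). Of 19 genes of the fatty acid synthesis list, 1 fell, TMEM97 (-0.56), which is a regulator of cholesterol handling and not an enzyme of fatty acid synthesis, and it fell also over the list alone (median -0.20, camera adjusted p = 0.342, past the threshold without control replicate 3, range 0.0180 to 0.667). Of 19 fatty acid oxidation and PPARA target genes, 2 rose, among them FABP1 (0.73), and 0 fell, and 5 rose when adjusted over the list alone (median 0.11, camera adjusted p = 0.0641, past the threshold with quantile normalization and without control replicate 3 or knockdown replicate 1, range 0.00216 to 0.193). Of 26 hypoxia response genes, CA9 rose from 0.157 to 3.42 (1.79, adjusted p = 0.0278), also over the list alone (median 0.05, camera adjusted p = 0.225). Of 19 YAP target genes, TGFB2, F3 and NUAK2 (1.23) rose and 2 fell, among them NT5E, and 3 rose and 3 fell when adjusted over the list alone; their median was -0.009, their mean 0.10 and camera's direction up (adjusted p = 0.624), with a median above 0 under quantile normalization and the rescaling. Of 12 Wnt and beta-catenin target genes, MYC rose (0.97) and BMP4 fell (-0.70), and 2 rose and 2 fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.501, past the threshold without knockdown replicate 1, range 0.0351 to 0.649). Of 10 integrin genes, ITGA5 rose and ITGAE (-0.56) fell, also over the list alone (median 0.22, camera adjusted p = 0.260). Of 17 chondroitin sulfate synthesis enzymes, CHST3 (-0.96) and B3GAT3 (-0.49) fell and 0 rose, and 1 rose and 2 fell when adjusted over the list alone (median 0.07, camera adjusted p = 0.624).

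Of the tests below, that of length and abundance was written before its result was seen, and all others after. The real grouping gave 1107 changed genes, against 0 at the highest in the other splits of the libraries into 3 and 3, 894 against 0 for changes of at least 1.5-fold, and 22 against 19 for called lists. In each case 1 of the 10 splits, the real one, reached its own count, and 10 splits are too few for a share under 0.05.

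Leukocyte transcripts appeared in knockdown replicate 2. Of 13 leukocyte markers fixed beforehand, 4 are expressed at 1 or more in a control library. LYZ, 1 of these, was at 44.5 and 37.8 in knockdown replicates 1 and 3, against at most 24.8 in control libraries. The other 9 cover myeloid, T, NK and B cells. Of these 9, 0 exceeded each control library in both knockdown replicates 1 and 3, which argues against their induction by the knockdown. Of the same 9, 8 had their highest value in knockdown replicate 2, against 1.5 expected by chance. Among the leukocyte genes far higher there than in any other library were S100A9 (30.6), S100A8 (17.9), HLA-DRA (11.7) and PPBP (11.4), chosen after their values were seen, and 29 protein-coding genes had a value of at least 1 there and at most 0.2 in any other library, against 1 or 2 in each of the others. RNA of leukocytes from outside the culture, taken up at RNA or library preparation or by misassigned reads, is a candidate source, as a hypothesis found and tested on the same data.

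The NF-kB and inflammatory genes were higher in the knockdown libraries. Leukocyte RNA in knockdown replicate 2 does not account for this: in the lower of knockdown replicates 1 and 3, which lack those transcripts, the list averaged 0.68 above the control mean, against an SD of 0.14 between control libraries. Both groups received lentivirus, so an interferon response to virus that was alike in both would not appear as a difference. An interferon response to lentivirus or double-stranded RNA that differed between the groups stays open. The interferon list had a median of 0.23, below 0.56, which is 0.5 of the NF-kB median. Its quartiles spread by 0.36 around that, so the list cannot decide. GBP1, an interferon-inducible gene outside that list, rose by 3.11, while 1 of the 20 list genes tested passed. An effect of the versican knockdown and an off-target effect of the single hairpin may each remain, and the design cannot separate them.

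Mitochondrially encoded transcripts were higher in the knockdown libraries by a median of 0.72. One scaling factor per library would move nuclear genes alike, and the median of 13683 nuclear genes was -0.0294 (quartiles -0.26 and 0.22). A bias for short or abundant genes would raise short, abundant nuclear genes. The 107 of 0.2 to 2 kb with a mean log2 value of at least 10 had a median of -0.17 (quartiles -0.28 and -0.08). MT-CYB and MT-CO3 had mean log2 values of 12.8 and 14.1, which the 107 need not reach, so a bias at those levels is not excluded. More mitochondrial and nuclear-retained RNA relative to cytoplasmic mRNA stays open. The 6 long non-coding RNAs taken as nuclear-retained had a median of 0.37, with MALAT1 at 1.43 (184 to 496, limma adjusted p = 0.0210). Of these 2 were lower, and OIP5-AS1 fell by 0.63 (limma adjusted p = 0.0245). Where each of these RNAs lies in Huh7 cells was not measured, so their values cannot decide. A change in mitochondrial transcription with the knockdown was not tested and stays open.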
